A study of Danio rerio with 1006 samples.

How the data were processed

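Whole-body RNA of zebrafish embryos of the AB strain was sequenced after exposure to PFOS, PFOA or PFHxS at up to 8 concentrations per compound, to 0.33% DMSO as the vehicle, or to 1 µM chlorpyrifos as a positive control for transcription, in 7 exposure windows. Libraries were made with the Lexogen CORALL kit, which marks each RNA molecule with a unique molecular identifier (UMI), per the labels' protocols. The deposited tables hold UMI counts per gene, whole numbers that were not normalized, for 47046 genes in 1006 libraries. The tools named with these counts are bcl2fastq 2.20.0, FastQC 0.11.9, MultiQC 1.14, fastp 0.23.2, STAR 2.7.10a and edgeR, with the genome build GRCz11, per the submitters' processing notes. Those notes give neither their order nor the settings, and the annotation and the use of strand in counting are not given in the sources used here. A second kind of table, deposited per compound and window, holds normalized values on a log2 scale, which the file names call filtered, raised by 1 and normalized. In each of the 21 tables the values equal the log2 of 1 plus the count times a single factor per library, which was not compared with TMM, and they were used in no test.

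Genes are named as in the deposited tables. Of the IDs, 32982 carry a symbol and 14064 are clone-type or provisional names, which were counted but not named. There are 22891 IDs equal to a symbol in the RefSeq assembly GRCz12tu, which was used for names only, so no coordinates are given. An ID with a suffix such as _1 is taken here as a further copy of the same symbol, which was not tested, nor was whether reads are shared between such copies. The first 4 lines of each count table name no gene. They held a median of 46.717% of all counts in a library, made up mostly of multimapping (23.582%), featureless (12.764%) and unmapped reads (10.293%), and stayed out of library sizes and tests.

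Groups, concentrations and windows were taken from the labels. The 14 libraries of a standard RNA pool entered no comparison. Of the remaining 992 libraries, 33 are labelled as repeats, and 32 of these have a first library of the same embryo. Counts of such pairs were summed, which left 960 embryos in 179 groups. No 2 libraries held identical counts. Library depth ranged from 2056470 to 12886766 UMIs in genes, with a median of 6195944.5. The test was tried on counts simulated from the mean levels of the DMSO embryos of 6-120 hpf, with 21599 genes. With changes put into the PFOS 20825 µg/L group, it called 22% of genes changed 1.5-fold. It called 76% of those changed 2-fold and 100% of those changed 3-fold, and 5.7% of its calls were false. In the PFOA 57325 µg/L group, with no change put in, it called 0 genes. The simulated embryos varied independently, with the same dispersion for every gene. No outlying embryo and no difference between sets of DMSO embryos was put in, so these rates do not measure false calls among the real embryos.

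Counts were tested with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr, TMM scaling, 1 quasi-likelihood model per window over all its groups, and Benjamini-Hochberg adjustment over all genes tested, with calls at an adjusted p under 0.05. The p-values in the text are from this test unless another is named. Levels are CPM on TMM-scaled library sizes, and errors are standard errors for log2 fold changes and SD for levels. The comparison taken for each compound before the data were examined was its highest concentration with libraries in all windows, 20825 µg/L for PFOS, 57325 µg/L for PFOA and 65395 µg/L for PFHxS, against the DMSO embryos of the window. Compounds were compared with each other at 20825 µg/L PFOS, 15875 µg/L PFOA and 23251 µg/L PFHxS, and windows by an interaction term in a joint model. Fixed lists of genes, 26 in number with 589 entries of which 565 were matched, 11 of them by a synonym, were tested with camera in limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation. The list of mitochondrial genes matched no ID, so 25 lists were tested.

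A transcriptomic point of departure (tPOD), the concentration at which a set share or number of genes begins to respond, was computed per compound and window. Genes entered it with an F-test over concentrations at an adjusted p under 0.05 and a change of at least 1.5-fold. Each gene's benchmark dose was the concentration at which a fitted curve leaves its own fitted level without exposure by 1 DMSO SD. The tPOD is the 25th lowest of these, and its interval is the 95% range of 100 bootstraps of the embryos, with the genes kept fixed. On simulated dose series, 97.5% of fitted benchmark doses lay within 3-fold of the true one. Those true doses all lay far above the lowest concentration and followed a single curve shape that was among those fitted. Benchmark doses near or below the lowest concentration were thus not tried.

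Genes named in the text follow a rule. Named are up to 8 largest rises and 8 largest falls per compound in 4 windows (and for chlorpyrifos in 2), among called genes with an average log2 CPM of at least 2 and every treated embryo on the same side of the DMSO mean. Added are up to 10 genes per compound called in the most windows, up to 3 per direction in each comparison of compounds or windows, and members of the fixed lists. For 1 fixed list, a result with PFHxS is not reported here. Other genes named in the closing section were chosen after their values were seen, and it says so. Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, no filter on low counts, repeat libraries left out, only the compound's own groups and DMSO in the model, the replicate number as a block, either set of DMSO embryos coded VA or VB alone, and each treated embryo number left out of all treated groups in turn. Treated embryos share a number only with DMSO embryos coded VA, so within a window the block compares them with VA embryos alone. Tables were handled with the R package data.table (version 1.17.8) and with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots drawn with matplotlib 3.10.9. The series text places each concentration on 2 of 3 plates, but the labels give no plate, so plates entered no model.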

Results

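The series asked how far the transcriptomic point of departure (tPOD) of 3 perfluoroalkyl acids in zebrafish varies with the part of development over which the embryos are exposed. PFOS and PFHxS are perfluoroalkyl sulfonates, PFHxS with the shorter chain, and PFOA is a perfluoroalkyl carboxylate. Exposure ran from 6 to 24, 6 to 48, 24 to 48, 6 to 120, 24 to 120, 48 to 120 or 96 to 120 hours post fertilization (hpf), and RNA was taken at its end. After repeat libraries were joined, the data held 264 embryos exposed to PFOS, 279 to PFOA, 279 to PFHxS, 117 to DMSO and 21 to chlorpyrifos, an organophosphate that inhibits acetylcholinesterase. Of the 165 groups of 1 compound, concentration and window, 162 held 5 embryos and 3 held 4. Each window had 16 DMSO embryos, except 6-48 hpf with 21, and 3 chlorpyrifos embryos. PFOS at 74407 µg/L had libraries only in the windows 6-24, 6-48, 24-48 and 96-120 hpf.

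Median depth differed between compounds in every window. In 6-120 hpf it was 4343795 UMIs in genes for PFOS, 7145449 for PFOA, 6922797 for PFHxS, 6285025 for DMSO and 3974145 for chlorpyrifos. The biological coefficient of variation was 13.9% among the 14 standard pool libraries, which hold technical spread alone, and between 19.8% and 24.2% among the DMSO embryos of a window. The labels call the samples biological replicates but give no clutch, plate or day, so the p-values measure only the spread between these embryos, part of which may be technical. DMSO embryos carry the codes VA or VB, whose meaning the labels do not state. In the 6-24 hpf window, 1101 of 17062 genes differed between its 9 VA and 7 VB embryos by edgeR, 457 of them higher in VA. In each of the other windows at most 4 genes differed by edgeR. At an unadjusted p under 0.05 the numbers were 2252 of 18738 in 48-120 hpf and 1576 of 17302 in 24-48 hpf. The remaining windows had between 860 and 1120. Few calls thus do not show that the VA and VB embryos were alike there.

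Embryos exposed to PFOS from 6 to 24 hpf had low levels of genes of the heart muscle. At 20825 µg/L the ventricular myosin heavy chain gene vmhc stood at 13.3 ± 3.43 CPM (SD, n = 5) against 87.9 ± 38.9 in DMSO (n = 16), a log2 fold change of -2.75 ± 0.47 (adjusted p = 0.00013). The atrial myosin heavy chain gene myh6 fell by 2.68 on the log2 scale (adjusted p = 0.00017). The cardiac troponin T gene tnnt2a fell by 2.38 (adjusted p = 0.00019) and the cardiac myosin light chain gene cmlc1 by 2.21 (adjusted p = 0.00023). PFOA at 57325 µg/L lowered the same list of heart muscle genes, with myh6 at 3.91 ± 0.772 CPM against 20.6 ± 8.3 (log2 fold change -2.41 ± 0.41, adjusted p = 0.00024) and vmhc at -2.15 ± 0.42 (adjusted p = 0.0026). Of the 11 measured heart muscle genes, 8 fell with PFOS and 8 with PFOA (8 and 9 when adjusted over the list alone), and the list's shift held with an estimated correlation (adjusted p = 0.037 for PFOS and 0.046 for PFOA). With PFHxS at 65395 µg/L none of the 11 was called by edgeR, and vmhc stood at a log2 fold change of -0.41 ± 0.36 (adjusted p = 0.76).

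Beyond the heart, PFOS in the 6-24 hpf window raised ntd5 to 48.8 ± 16.4 CPM from 22.3 ± 7.52 (log2 fold change 1.16 ± 0.19, adjusted p = 6.2e-05), the hyaluronan synthase gene has2 (1.18 ± 0.25) and sfrp2 (1.25 ± 0.24), which codes for a secreted Wnt antagonist. PFOA lowered gys2, the liver form of glycogen synthase, by 2.18 on the log2 scale (adjusted p = 0.0048) and raised her3 (0.86 ± 0.21, adjusted p = 0.012). The hepatocyte list had 7 of 17 members lower with PFOS (10 adjusted over the list alone) and 5 with PFOA (10 over the list alone), and its shift did not hold with an estimated correlation (adjusted p = 0.24 and 0.059). Cytosolic ribosome genes rose in 15 of 32 cases with PFOS, 23 when adjusted over the list alone, also without holding (adjusted p = 0.38 with an estimated correlation). With PFOS 4 of 22 skeletal muscle genes fell and 1 rose (8 and 2 over the list alone), and 4 of 21 cholinergic and neuronal genes fell (5 over the list alone), without holding (adjusted p = 0.57 and 0.44 with an estimated correlation). The mitochondrial ribosomal RNA mt-rnr1 fell with PFOS (-1.87 ± 0.49, adjusted p = 0.009), PFOA (-1.74 ± 0.49, adjusted p = 0.034) and chlorpyrifos (-2.53 ± 0.66, adjusted p = 0.025). In all, PFOS called 1036 genes up and 1029 down and PFOA 229 up and 287 down. PFHxS called 0 genes by edgeR, against 2035 genes at an unadjusted p under 0.05 and 1 by DESeq2.

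These 6-24 hpf counts rest on which DMSO embryos are taken. Against the 7 VB embryos alone PFOS called 46 genes and PFOA 75, against the 9 VA embryos alone 3875 and 1693, and PFHxS 0 and 444. The fall of myh6 held against VB alone with PFOS (-2.41 ± 0.52) and PFOA (-2.14 ± 0.46). So did the fall of vmhc (-2.13 ± 0.50) and the rise of ntd5 (0.89 ± 0.22) with PFOS and the rise of her3 with PFOA (1.00 ± 0.25). The fall of mt-rnr1 was smaller and not called against VB alone (-0.38 ± 0.42 with PFOS, -0.25 ± 0.42 with PFOA and -1.05 ± 0.53 with chlorpyrifos), and against VA alone it was called with PFHxS too (-1.74 ± 0.46). The calls of the remaining genes named above ended against VB alone, with fewer controls and folds of the same direction: tnnt2a (-1.74 ± 0.45), cmlc1 (-1.73 ± 0.44), has2 (0.86 ± 0.29) and sfrp2 (0.91 ± 0.27) with PFOS, and vmhc (-1.52 ± 0.45) and gys2 (-1.76 ± 0.53) with PFOA. The losses of these 6 calls alone do not show that the changes rest on the VA embryos. Of the heart muscle genes 2 stayed called with PFOS and 1 with PFOA. With PFOS 0 of 32 ribosome genes and 0 of 17 hepatocyte genes were called by edgeR against VB alone, and 23 and 8 against VA alone. Likewise 0 of 22 skeletal muscle and 0 of 21 cholinergic and neuronal genes were called by edgeR against VB alone. Against VA alone 9 and 7 fell, and 2 skeletal muscle genes rose. The call of sfrp2 also ended without embryo 1 and that of her3 without embryo 5. Without embryo 1 of each treated group the counts were 570 for PFOS and 133 for PFOA. Neither compound showed a gradient with concentration in this window: all 8 concentrations of PFOS called between 64 and 2065 genes and all 8 of PFOA between 288 and 2834, while a trend over concentrations among the treated embryos alone was found in 3 genes for each.

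Chlorpyrifos from 6 to 24 hpf raised aifm4 to 32.3 ± 13.4 CPM (n = 3) from 11.4 ± 2.54 in DMSO (log2 fold change 1.52 ± 0.22, adjusted p = 2.3e-06). It raised msgn1, a transcription factor gene of the presomitic mesoderm (1.60 ± 0.40, adjusted p = 0.019), and elf3 (1.54 ± 0.32, adjusted p = 0.0049). Genes of fast skeletal muscle were lower, among them myhz1.2 at 218 ± 21.2 CPM against 819 ± 519 (-1.91 ± 0.53, adjusted p = 0.033) and mybpc2b (-1.71 ± 0.43, adjusted p = 0.021). Of 22 skeletal muscle genes, 4 fell (13 adjusted over the list alone, with 1 higher), and the list's shift did not hold (adjusted p = 0.66 with an estimated correlation). By edgeR against VB alone 0 of the 22 were called, and against VA alone 10 fell and 1 rose. Of 32 cytosolic ribosome genes 8 rose, with 0 against VB alone and 17 against VA alone. Chlorpyrifos called 314 genes up and 146 down here. The count was 30 without embryo 3 and 5 against the VB embryos, and of 16 genes named by the rule aifm4 alone held with each embryo left out and against VB (1.41 ± 0.25). DESeq2 called 1138 genes.

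At the concentrations compared, exposures that ended at 48 hpf changed few genes. Calls were more at some lower concentrations, up to 570 with PFHxS at 15 µg/L in 6-48 hpf and 627 with PFHxS at 1790 µg/L in 24-48 hpf. The first was 48 without embryo 1 and 22 against the VB embryos alone, and the second 186 without embryo 3 and 268 against the VA embryos alone. PFOS at 20825 µg/L from 6 to 48 hpf raised fosab (24.6 ± 9.36 CPM, n = 5, against 10.4 ± 4.73, n = 21, log2 fold change 1.27 ± 0.27, adjusted p = 0.012), fosl2 (1.02 ± 0.21, adjusted p = 0.0082), junbb (0.97 ± 0.17, adjusted p = 0.00094) and atf3 (0.94 ± 0.21, adjusted p = 0.028), which code for transcription factors, and the fibronectin gene fn1b (1.00 ± 0.22, adjusted p = 0.023). The colony-stimulating factor gene csf1a fell by 0.82 (adjusted p = 0.032). Each of these 6 calls ended without embryo 2. In the list of innate immune and acute phase genes, 1 of 17 rose (4 adjusted over the list alone), namely stat3 by 0.58, and the list's shift held with an estimated correlation (adjusted p = 0.02). PFHxS at 65395 µg/L lowered kcnj1a.2, which codes for an inwardly rectifying potassium channel, to 1.79 ± 0.516 from 7.18 ± 2.47 CPM (-2.03 ± 0.35, adjusted p = 0.00065). In the 24-48 hpf window kcnj1a.2 fell with PFOS by 2.06 ± 0.39 (adjusted p = 0.014) and with PFHxS by 2.01 ± 0.36 (adjusted p = 0.0035), while with PFOA it stood at -0.02 ± 0.25 (adjusted p = 0.99).

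In the 6-48 hpf window PFOS called 15 genes up and 2 down and PFHxS 2 up and 1 down. PFOA called 0 by edgeR (2108 at an unadjusted p under 0.05, 17 by DESeq2), and chlorpyrifos 0 (982 and 0). In the 24-48 hpf window PFOS called 1 up and 1 down, PFHxS 0 up and 2 down, PFOA 0 (2008 at an unadjusted p under 0.05, 5 by DESeq2) and chlorpyrifos 0 (1024 and 0). The PFOS count in 6-48 hpf was 3 without embryo 2 and 1 against the VA embryos alone, and in both settings none of the 10 genes named by the rule was called. For kcnj1a.2 with PFHxS the call held in every setting in 6-48 hpf. In 24-48 hpf it ended without embryo 1 or 4 and against the VB embryos alone, and with PFOS it ended without embryo 1, 2, 3 or 4 and with only the PFOS groups and DMSO in the model. Against the VB embryos alone PFOS called 17 and PFOA 57 genes in 24-48 hpf.

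Exposure from 6 to 120 hpf to PFOS at 20825 µg/L lowered kcnj1a.2 to 3.68 ± 2.77 CPM (n = 5) from 44.9 ± 9.19 in DMSO (n = 16), a log2 fold change of -3.73 ± 0.28 (adjusted p = 1.8e-20). The annexin gene anxa1b fell by 2.80 ± 0.35 (adjusted p = 1.2e-09). The gene pnpla1, whose human counterpart is needed for the skin's lipid barrier, stood at -4.19 ± 0.73 (adjusted p = 1.1e-05). The neuronal activity-regulated transcription factor gene npas4a rose to 80.0 ± 58.6 from 14 ± 3.49 CPM (2.47 ± 0.22, adjusted p = 3.6e-16) and the orphan nuclear receptor gene nr4a3 by 1.71 ± 0.15 (adjusted p = 1.7e-17). The cytochrome P450 gene cyp2k18 rose by 2.7 ± 0.28 (adjusted p = 9.1e-13), the amino acid transporter gene slc6a19a.1 by 1.71 ± 0.26 (adjusted p = 8e-07) and rhcgl1, an ammonia transporter gene, by 4.71 ± 0.51 (adjusted p = 4.6e-13). The ID rhcgl1_1 stood at 3.25 ± 0.51.

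Groups of genes moved with PFOS in this window. Of 24 measured genes of xenobiotic metabolism, 12 rose (13 adjusted over the list alone, with 1 lower), and the list's shift held with an estimated correlation (adjusted p = 0.014). Among them were cyp3a65 (1.62 ± 0.30), the glucuronosyltransferase gene ugt1a1 (1.25 ± 0.24) and the efflux transporter gene abcc2 (1.31 ± 0.23). Of 35 genes of fatty acid oxidation and PPAR targets, 8 rose (13 over the list alone, adjusted p = 0.02 with an estimated correlation). They include cpt1b, which carries fatty acids into mitochondria (0.94 ± 0.14), acadvl (0.47 ± 0.08) and pdk4 (0.82 ± 0.13). Of 23 cholinergic and neuronal genes, 10 rose (14 adjusted over the list alone), such as gad2 (0.64 ± 0.12) and nefmb (0.67 ± 0.15). This shift did not hold (adjusted p = 0.24 with an estimated correlation). Among 21 glucocorticoid and hypoxia genes 6 rose and 1 fell (7 and 1 over the list alone), with pck1 at 1.52 and igfbp1a at 1.37. The list's shift did not hold (adjusted p = 0.32 with an estimated correlation).

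PFOA at 57325 µg/L over the same window raised cyp2k18 to 179 ± 54.9 CPM (n = 5) from 8.18 ± 5.21 (n = 16), a log2 fold change of 4.44 ± 0.25 (adjusted p = 1.9e-30). The genes cyp3a65 (715 ± 279 against 131 ± 82.4 CPM, 2.44 ± 0.29, adjusted p = 6e-10), ugt1a1 (2.24 ± 0.20, adjusted p = 7.7e-16), ugt1ab (1.88 ± 0.25, adjusted p = 1.1e-08) and abcc12 (1.75 ± 0.17, adjusted p = 1.1e-14) rose, and so did alas1, the first enzyme of heme synthesis (1.63 ± 0.21, adjusted p = 9.8e-09). Of the 24 genes of xenobiotic metabolism 10 rose (12 adjusted over the list alone, adjusted p = 9.9e-05 with an estimated correlation). Of 24 oxidative stress genes 5 rose (9 over the list alone, with 1 lower, adjusted p = 0.036 with an estimated correlation), among them gstp2 (1.17), me1 (0.95) and the glutamate-cysteine ligase gene gclc (0.52). Of 16 genes of cartilage, bone and notochord 6 rose (8 over the list alone), without holding (adjusted p = 0.11 with an estimated correlation). The 8 largest rises by the rule held in every setting, whereas of the 8 largest falls cbln18 (-1.32 ± 0.28) alone held with each embryo left out, and it did not hold against the VB embryos (-1.07).

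PFHxS at 65395 µg/L lowered kcnj1a.2 to 2.12 ± 0.885 CPM (n = 5, -4.35 ± 0.29, adjusted p = 4.8e-25), anxa1b by 1.67 ± 0.30 (adjusted p = 3e-04) and the somatostatin gene sst2 by 1.65 ± 0.32 (adjusted p = 0.00071). It raised cyp2k18 (3.05 ± 0.27, adjusted p = 8.5e-17), cyp3a65 (1.67 ± 0.30, adjusted p = 0.00028), ugt1a1 (1.63 ± 0.22, adjusted p = 4.9e-08), abcc2 (1.22 ± 0.23, adjusted p = 0.00039) and abcb11b, the bile salt export pump gene (1.22 ± 0.20, adjusted p = 2.3e-05). Of the 24 genes of xenobiotic metabolism 7 rose (12 adjusted over the list alone, adjusted p = 0.00025 with an estimated correlation). Chlorpyrifos raised fosl1a (2.32 ± 0.39, adjusted p = 0.00026), epgn (1.16 ± 0.26, adjusted p = 0.042), cebpb (0.95 ± 0.19, adjusted p = 0.017) and adamts1 (0.87 ± 0.19, adjusted p = 0.042) in 3 embryos, and none of these 4 calls held with each embryo left out in turn. Without embryo 2 chlorpyrifos called 2 genes.

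In the 6-120 hpf window PFOS called 825 genes up and 619 down, PFOA 323 and 193, PFHxS 89 and 30, and chlorpyrifos 10 and 0. Without embryo 3 the PFOS count was 708, without embryo 5 the PFOA count was 196 and the PFHxS count 61, and against the VB embryos alone the counts were 842, 175 and 56. Counts did not rise evenly with concentration. For PFOS they were 1444 at 20825 µg/L, 102 at 6386, 0 at 1639 and 506, 4 at 113, 21 at 33 and 1593 at 7. The 2 counts of 0 by edgeR stood beside 2305 and 1596 genes at an unadjusted p under 0.05, and 55 and 0 by DESeq2. For PFOA counts were 516 at 57325 µg/L, 365 at 15875, 15 at 6461, 76 at 52 and 1114 at 16, with 0 at 1687, 571 and 160 (1795, 2600 and 2321 at an unadjusted p under 0.05, and 0, 8 and 0 by DESeq2).

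**Figure D1:**
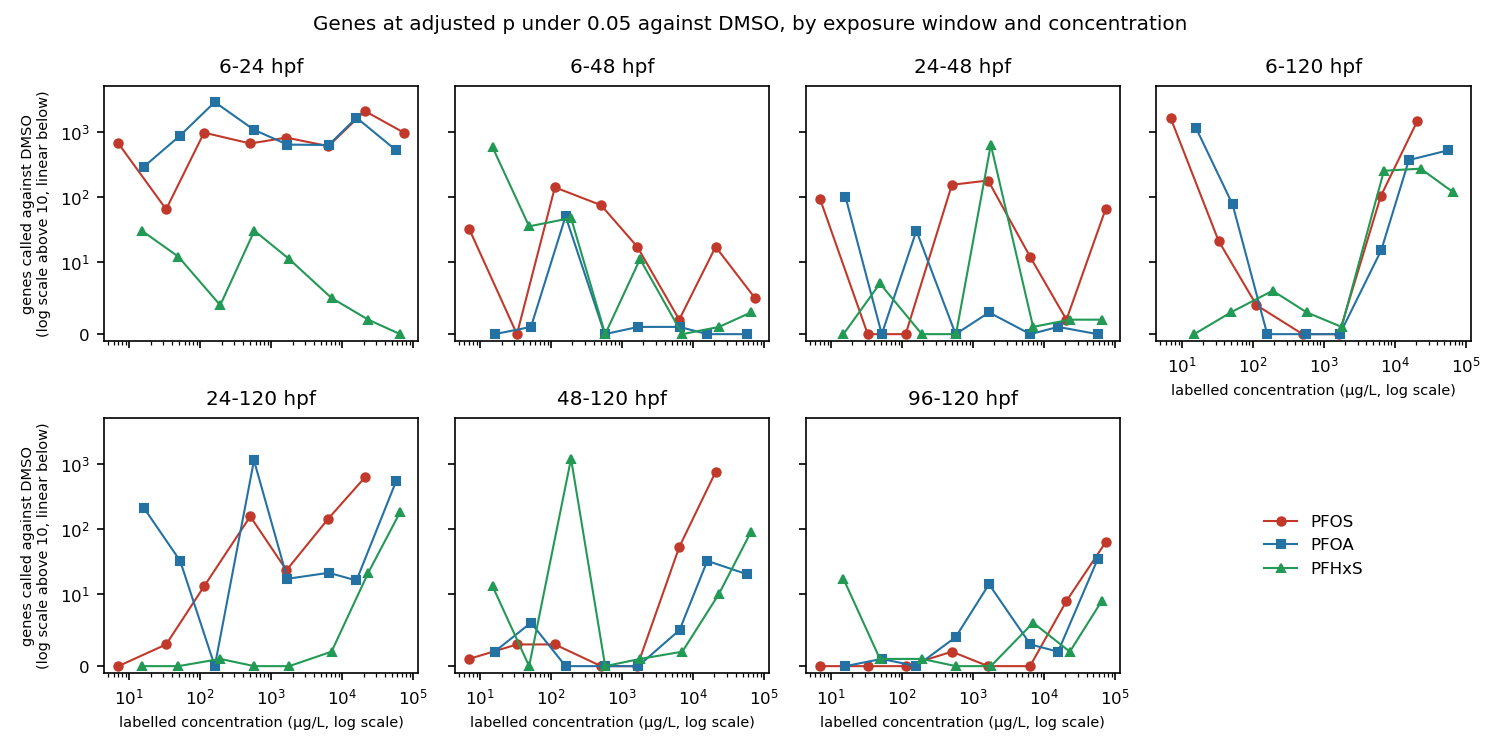
Number of genes at an adjusted p under 0.05 against the DMSO embryos of the window (edgeR), by concentration in µg/L on a log scale, with 1 panel per exposure window and 1 line per compound. The vertical axis is linear below 10 and logarithmic above. In 6-120 hpf the PFOS line runs from 1593 at 7 µg/L through 0 to 1444 at 20825 µg/L.

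The genes shared between compounds in 6-120 hpf were counted with the shared DMSO embryos in mind. PFOS and PFOA had 134 raised and 66 lowered genes in common, where independent lists would share 11.5 and 5.2, and PFOS and PFHxS had 56 and 22 in common against 3.2 and 0.8. PFOA and PFHxS shared 50 raised genes against 1.2 and 3 lowered genes against 0.3. When each compound was compared with other DMSO embryos than its partner, PFOS and PFOA shared 52 or 72 raised and 18 or 33 lowered genes, PFOS and PFHxS 24 or 32 and 10 or 16, and PFOA and PFHxS 25 or 32 and 1 or 0. The numbers for independent lists are from the full lists, and none was computed for these split lists.

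Later starts of exposure left the main genes of 6-120 hpf in place. With PFOS, kcnj1a.2 fell by 3.03 ± 0.32 in 24-120 hpf (adjusted p = 4.6e-12) and by 2.76 ± 0.29 in 48-120 hpf (adjusted p = 2.7e-12), and anxa1b by 2.25 ± 0.33 and 2.41 ± 0.31. With PFHxS kcnj1a.2 fell by 3.67 ± 0.32 and 4.04 ± 0.33 (adjusted p = 2.2e-16 and 5.8e-19), and sst2 by 1.98 ± 0.32 and 1.94 ± 0.32. PFOA raised cyp2k18 by 4.05 ± 0.26 and 3.88 ± 0.22 (adjusted p = 6.8e-26 and 1.3e-29), mgst3b, a microsomal glutathione transferase gene, by 0.99 ± 0.10 and 0.67 ± 0.10, and abcc12 by 1.3 ± 0.17 and 0.86 ± 0.16. These calls held in every setting, except that of abcc12 in 48-120 hpf, which ended without embryo 1, against the VA embryos alone and with the replicate number as a block. Xenobiotic metabolism genes rose in 10 of 23 cases with PFHxS and 8 of 23 with PFOA in 24-120 hpf (11 and 13 adjusted over the list alone, adjusted p = 5.5e-05 and 2e-04 with an estimated correlation), and in 6 of 23 with PFHxS in 48-120 hpf (9 over the list alone, adjusted p = 0.0073).

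In 48-120 hpf, 24 of 32 cytosolic ribosome genes rose with PFOS (30 adjusted over the list alone), for example rps7 (0.42 ± 0.08) and rpl5a (0.32 ± 0.06). The list's shift did not hold (adjusted p = 0.093 with an estimated correlation). The growth factor binding protein genes igfbp1b (2.21 ± 0.33, adjusted p = 7.5e-07) and igfbp1a (1.53 ± 0.28, adjusted p = 7e-05) and the glucocorticoid-responsive gene fkbp5 (adjusted p = 0.00043) also rose with PFOS. In their list 5 of 21 rose and 1 fell (10 and 1 over the list alone, adjusted p = 0.15 with an estimated correlation). The call of igfbp1b ended without embryo 4, those of rps7 and fkbp5 against the VA embryos alone, and those of rps7, rpl5a and igfbp1a with the replicate number as a block. PFHxS raised 4 of 24 genes of cholesterol synthesis (9 over the list alone, adjusted p = 0.034 with an estimated correlation): sqlea by 1.84 ± 0.39, cyp51 by 1.25 ± 0.28, mvda by 1.02 ± 0.26 and hmgcs1 by 0.74 ± 0.16. All 4 calls ended without embryo 1 or 3 and against the VB embryos alone, and that of mvda also without embryo 2, by DESeq2 and with only the PFHxS groups and DMSO in the model. In 24-120 hpf PFOA lowered 6 of 24 cholinergic and neuronal genes (9 over the list alone), such as sncb by 0.40 ± 0.09 and gap43 by 0.44 ± 0.11, without holding (adjusted p = 0.15 with an estimated correlation). It raised 3 of 24 oxidative stress genes (7 over the list alone, adjusted p = 0.046 with an estimated correlation), among them gpx1b (1.02) and gpx4a (0.90). The calls of sncb, gap43 and gpx1b ended without embryo 1, whereas that of gpx4a held in every setting. Chlorpyrifos in 24-120 hpf raised irg1l to 31.5 ± 24.3 (n = 3) from 3.94 ± 3.66 CPM (3.01 ± 0.44, adjusted p = 7.7e-07) and elf3 (1.68 ± 0.26, adjusted p = 3.9e-06), and both calls ended without embryo 1.

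Counts in 24-120 hpf were 338 up and 273 down with PFOS, 373 and 159 with PFOA, 141 and 38 with PFHxS and 50 and 33 with chlorpyrifos. In 48-120 hpf they were 540 and 206, 15 and 5, and 63 and 26, and chlorpyrifos called 0 by edgeR (1770 at an unadjusted p under 0.05, 13 by DESeq2). Without a single embryo number the 24-120 hpf counts went as low as 141 (PFOS, embryo 5), 156 (PFOA, embryo 4), 74 (PFHxS, embryo 5) and 6 (chlorpyrifos, embryo 1), and the 48-120 hpf counts to 342 (PFOS, embryo 4), 7 (PFOA, embryo 1) and 43 (PFHxS, embryo 2). Against the VB embryos alone they were 191 for PFOS and 320 for PFOA in 24-120 hpf, and against VA alone 75 for PFHxS. In 48-120 hpf PFOS called 172 against VA alone and 1205 against VB alone. Against VB alone PFHxS called 23 genes and chlorpyrifos 120 in this window.

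Exposure in the last day, from 96 to 120 hpf, changed few genes at the concentrations compared, with the same leading ones. PFOS at 20825 µg/L lowered kcnj1a.2 to 1.72 ± 0.845 from 16.4 ± 4.00 CPM (n = 5 and 16, -3.27 ± 0.38, adjusted p = 8.9e-10) and raised abcb11b (0.95 ± 0.18, adjusted p = 0.0031), a call that ended against the VA embryos alone (0.79). PFHxS lowered kcnj1a.2 to 0.565 ± 0.634 CPM (-4.99 ± 0.44, adjusted p = 1.1e-16), lowered rnf183 by 0.72 ± 0.12 (adjusted p = 0.00034) and raised cyp2k18 (1.71 ± 0.32, adjusted p = 0.0023). PFOA raised cyp2k18 to 107 ± 38.2 from 10.7 ± 4.66 CPM (3.32 ± 0.29, adjusted p = 4e-17), ugt1a1 (1.32 ± 0.28, adjusted p = 0.0078), alas1 (644 ± 188 from 292 ± 97.7 CPM, adjusted p = 0.021) and abcc12 (0.87 ± 0.16, adjusted p = 0.00088). Of 35 fatty acid oxidation genes 1 rose with PFOA (6 adjusted over the list alone, adjusted p = 0.046 with an estimated correlation). PFOS called 6 genes up and 3 down, and 57 up and 5 down at 74407 µg/L, PFOA 30 and 4, PFHxS 5 and 4, and chlorpyrifos 2 and 0 (36 in all by DESeq2). Without embryo 1 the counts were 3 for PFOS, 9 for PFOA and 4 for PFHxS, and without it the calls of ugt1a1 and alas1 with PFOA and of cyp2k18 with PFHxS ended.

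Across concentrations kcnj1a.2 fell with both sulfonates from the same range of concentrations. With PFOS at 6386 µg/L it was lower by 0.86 ± 0.19 in 6-120 hpf (adjusted p = 0.015), and at 74407 µg/L by 4.74 in 96-120 hpf, 2.11 ± 0.37 in 6-48 hpf and 2.2 ± 0.39 in 24-48 hpf. With PFHxS in 6-120 hpf the log2 fold change was -1.26 at 7061 µg/L and -3.42 at 23251 µg/L. With PFOA in 6-120 hpf it was -0.56 at 57325 µg/L (adjusted p = 0.069) and -0.76 at 15875 µg/L (adjusted p = 0.014). The rise of cyp2k18 began at similar concentrations of all 3 compounds: 2.18 at 6386 µg/L PFOS, 2.03 at 6461 µg/L PFOA and 1.85 at 7061 µg/L PFHxS in 6-120 hpf, all called by edgeR.

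**Figure D2:**
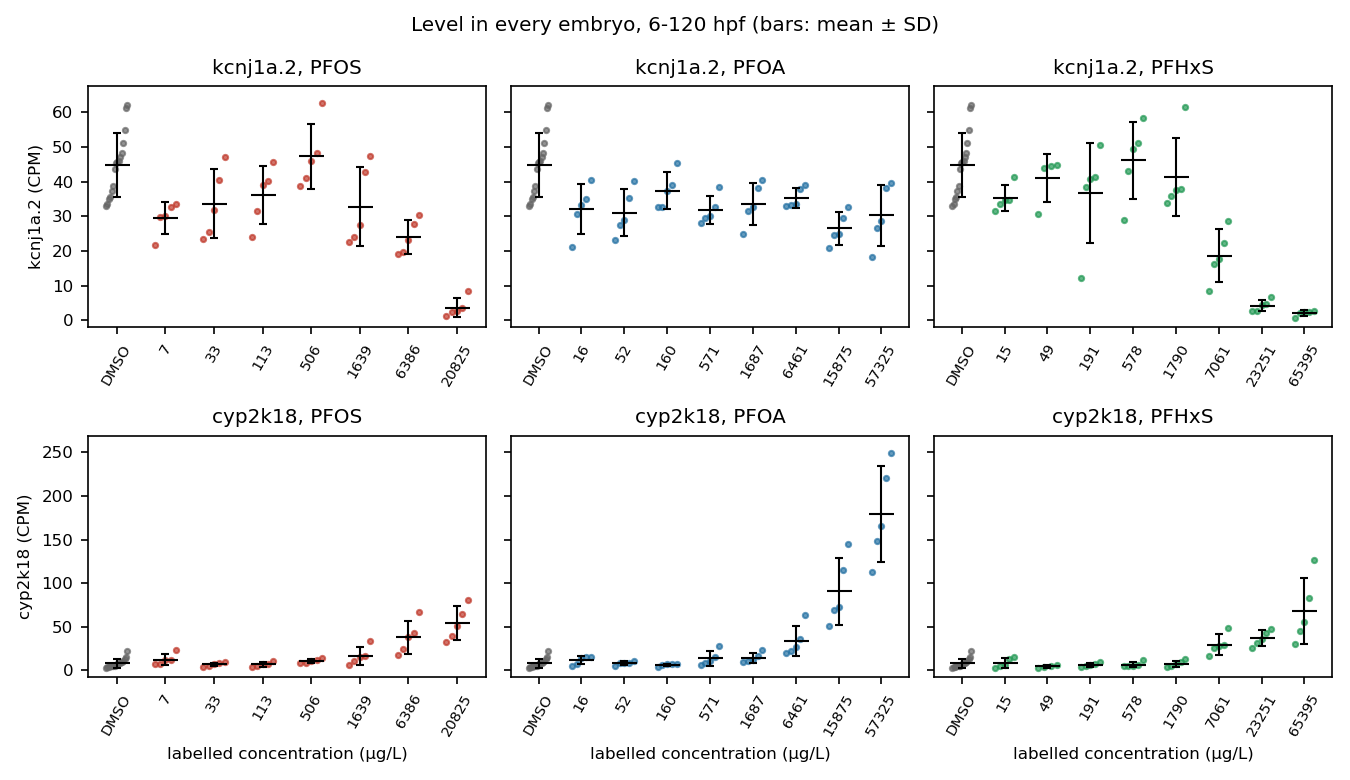
Levels of kcnj1a.2 and cyp2k18 in CPM in every embryo of the 6-120 hpf window, by concentration in µg/L, with DMSO at the left of each panel. Points are embryos and bars are the mean and SD. For kcnj1a.2 the DMSO mean is 44.9 and the mean at the highest concentration is 3.68 for PFOS and 2.12 for PFHxS, and for cyp2k18 the mean at the highest PFOA concentration is 179 against 8.18 in DMSO.

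Compounds were compared directly at 20825 µg/L PFOS, 15875 µg/L PFOA and 23251 µg/L PFHxS, which differ somewhat in mass concentration. In 6-120 hpf kcnj1a.2 was lower with the sulfonate PFOS than with the carboxylate PFOA by a log2 difference of -2.98 ± 0.32 (adjusted p = 9e-12) and higher with PFOA than with PFHxS by 2.66 ± 0.28 (adjusted p = 1.5e-11). PFOS and PFHxS differed by -0.32 (95% interval -1.12 to 0.48). PFOS exceeded PFOA in npas4a (2.28 ± 0.30, adjusted p = 4.8e-08), nr4a3 (1.89 ± 0.20, adjusted p = 3.1e-12), rhcgl1_1 (5.99 ± 0.96, adjusted p = 7.9e-06) and rhcgl1 (7.14 ± 0.95, adjusted p = 8.3e-09). PFOS exceeded PFHxS in nr4a3 (1.38 ± 0.19, adjusted p = 1.6e-06) and in the cytokine signalling inhibitor genes socs3a (2.12 ± 0.48, adjusted p = 0.0078) and socs1a (1.94 ± 0.42, adjusted p = 0.0055). The annexin gene anxa1b was lower with PFOS than with PFOA (-2.48 ± 0.38, adjusted p = 3.9e-06) and PFHxS (-1.66 ± 0.39, adjusted p = 0.014). No difference was called for cyp3a65 between PFOS and PFOA (-0.01, interval -0.80 to 0.77), for abcc12 (-0.12, interval -0.56 to 0.31) or for ugt1a1 (-0.45, interval -0.98 to 0.08), nor for cyp2k18 between PFOA and PFHxS (1.32 ± 0.32, adjusted p = 0.077).

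Between PFOS and PFOA 178 genes were higher with PFOS and 41 with PFOA in 6-120 hpf, between PFOS and PFHxS 103 and 45, and between PFOA and PFHxS 6 and 5 (30 in all by DESeq2). The counts were 70, 28 and 1 without embryo 3, and the calls of socs1a and anxa1b between PFOS and PFHxS ended without it, as did that of socs3a without embryo 5. In 6-24 hpf vmhc was lower with PFOS than with PFHxS (-2.47 ± 0.53, adjusted p = 0.036) and syngr3b higher (1.00 ± 0.20, adjusted p = 0.031), and both calls ended without embryo 1. PFOS and PFHxS differed there in 3 genes up and 1 down (11 in all by DESeq2). PFOS and PFOA differed in 0 by edgeR (1323 at an unadjusted p under 0.05, 1 by DESeq2) and PFOA and PFHxS in 0 (2569 and 2). The difference in vmhc was -0.05 (interval -1.2 to 1.1) between PFOS and PFOA.

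Responses were compared between windows that end at the same age. These windows differ in the age at first exposure as well as in length, so length alone was not tested. Each window also has its own embryos and its own DMSO. In DMSO kcnj1a.2 stood at 44.9 ± 9.19 CPM in 6-120 hpf and at 16.4 ± 4 CPM in 96-120 hpf. For PFOS, 76 genes responded more upward and 58 more downward in 6-120 than in 96-120 hpf. Among them were the calymmin gene cmn (2.54 ± 0.45, adjusted p = 0.0037), col9a1b_1, whose symbol is that of a collagen gene (2.41 ± 0.45, adjusted p = 0.0042), rhcgl1 (4.15 ± 1.03, adjusted p = 0.037), znf750, a transcription factor gene of epidermal differentiation (-1.41 ± 0.26, adjusted p = 0.0042), and anxa1b (-1.57 ± 0.40, adjusted p = 0.048). In 6-120 hpf cmn and col9a1b_1 were also raised at the lowest concentration, 7 µg/L PFOS (1.84 ± 0.31 and 1.55 ± 0.34). Their difference between windows is thus not shown to follow the concentration of PFOS. For kcnj1a.2 the difference between windows was -0.47 (interval -1.47 to 0.52) with PFOS and 0.64 (interval -0.61 to 1.90) with PFHxS. For cyp2k18 it was 1.15 (interval 0.36 to 1.95, adjusted p = 0.17), 1.12 with PFOA (interval 0.39 to 1.84, adjusted p = 0.24) and 1.34 with PFHxS (interval 0.53 to 2.15, adjusted p = 0.73). For PFOA 2 genes responded more upward and 8 more downward, with spon1a (0.87 ± 0.18, adjusted p = 0.04) and the pyruvate kinase gene pklr (-1.40 ± 0.29, adjusted p = 0.047) among them.

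The PFOS count of 134 was 43 without embryo 3, while cmn, col9a1b_1 and znf750 were called with each embryo left out. The PFOA count of 10 was 0 without embryo 1. DESeq2 called 383 and 89 genes. For PFHxS 0 genes differed by edgeR (1077 at an unadjusted p under 0.05, 0 by DESeq2). Between 6-48 and 24-48 hpf 0 genes differed for PFOS (1064), PFOA (929) or PFHxS (813 at an unadjusted p under 0.05), and 0 by DESeq2 for each.

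The tPOD was computed against all DMSO embryos of a window, not against VA or VB alone. Its dependence on them was thus not tested, also in 6-24 hpf, where calls rested on which were taken. The bootstrap range keeps the genes chosen on all embryos, so it leaves out that choice and the choice of controls. In 6-24 hpf the values of PFOS and PFOA lie below the lowest concentration tested. The tPOD of PFOS took different values between windows. It was 3.99 µg/L in 6-24 hpf (95% bootstrap range 2.64 to 4.76), 7.94 in 6-120 hpf (5.52 to 8.56), 48.2 in 24-120 hpf (10.5 to 52.6, and 27.1 without embryo 3 or 113 without embryo 5) and 37100 in 96-120 hpf (14000 to 52400). The last rests on 26 genes, lies above 20825 µg/L, the highest PFOS concentration of 6-120 and 24-120 hpf, and without embryo 1, 2, 3 or 5 fewer than 25 genes were left and there was none. Taken as the 10th percentile of benchmark doses, the PFOS tPOD in 96-120 hpf was 3040, below 20825. For windows ending at 48 hpf the range was wide, 39.7 to 12600 around 6560 in 6-48 hpf and 56.3 to 68100 around 527 in 24-48 hpf. In 6-48 hpf it was 17.5 without embryo 2 and 4220 without embryo 1. There was no tPOD in 6-48 hpf without embryo 5, nor in 24-48 hpf without embryo 1, 3, 4 or 5. PFOA had a tPOD of 10.3 in 6-24 hpf (6.29 to 13), 18.4 in 6-120 hpf (15.2 to 19.6) and 20.4 in 24-120 hpf (15.2 to 33.6). PFHxS had 1800 in 6-120 hpf (101 to 1830, and 999 without embryo 3 or 2920 without embryo 1) and 6660 in 24-120 hpf (1950 to 17600, and 2750 without embryo 2 or 19500 without embryo 5). In 48-120 hpf PFOS had 1360 and PFHxS 2940, both above their bootstrap ranges of 111 to 956 and 33.0 to 356. The tPOD there was 802 for PFOS without embryo 5, and for PFHxS 116 without embryo 1 and 13800 without embryo 5. In the other 4 windows of PFOA and the other 4 of PFHxS fewer than 25 genes gave a benchmark dose, so there was no tPOD.

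The F-test against DMSO also takes genes with no gradient among the treated embryos. For 6-24 hpf 839 genes gave a benchmark dose with PFOS and 846 with PFOA. A trend among the treated embryos was called in 3 genes for each. At most 3 of the 25 genes that set each of these tPODs thus had a called trend. Where a gene is flat among treated embryos, its benchmark dose is tied to the lowest concentration, 7 µg/L for PFOS and 16 for PFOA. These values therefore do not rank the compounds. Whether the values near the lowest concentration in other windows come from genes without a gradient was not settled. A choice of genes with a trend over concentrations among the treated embryos alone drops any gene that responds fully at the lowest concentration, so it does not settle this either. The curves of genes so chosen were fitted without the DMSO embryos, so they start from a level extrapolated from treated embryos. With those genes the tPOD was 2510 for PFOS in 6-120 hpf, 347 in 24-120 hpf, 768 in 48-120 hpf and 15100 in 96-120 hpf, for PFOA 5850 in 6-120 hpf and 48600 in 24-120 hpf, and for PFHxS 2650 in 6-120 hpf and 9060 in 24-120 hpf. In 6-24 hpf such genes numbered 3 for PFOS and 3 for PFOA and gave none. Without embryo 5 of the PFHxS 191 µg/L group the 48-120 hpf tPOD of PFHxS was 8030 and that of PFOS 357. PFOA then had a tPOD of 23400 in this window, from 34 genes.

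**Figure D3:**
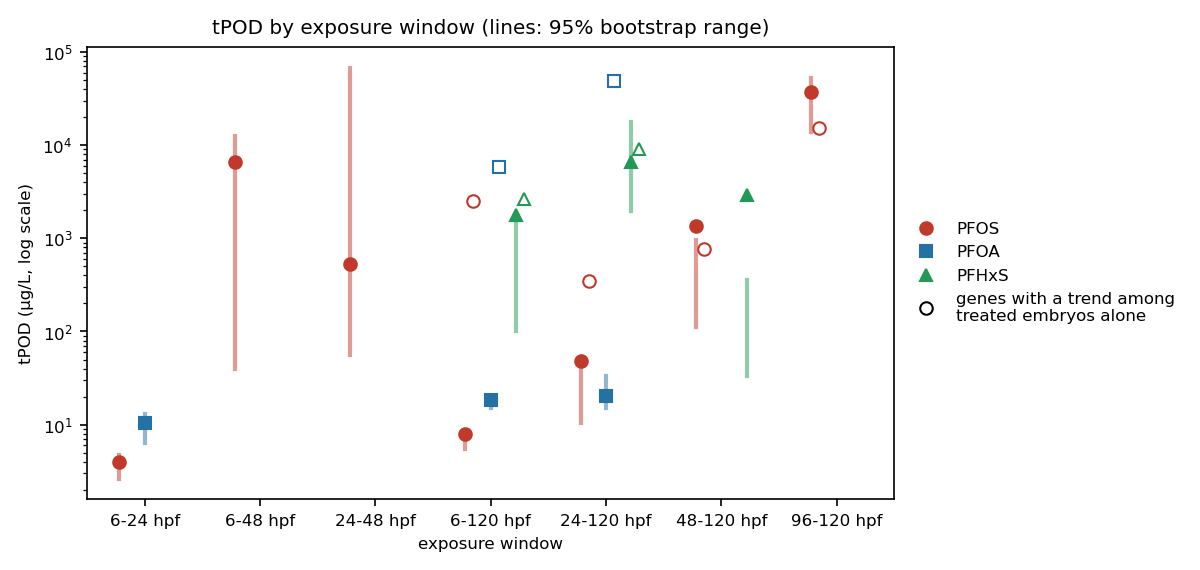
Transcriptomic point of departure in µg/L on a log scale by exposure window, for PFOS (circles), PFOA (squares) and PFHxS (triangles). Filled symbols are from genes with a difference over DMSO and all concentrations, lines are 95% bootstrap ranges, and open symbols are from genes with a trend among treated embryos alone. For PFOS in 6-120 hpf the filled symbol lies at 7.94 and the open symbol at 2510.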

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

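The tests of the VA embryos, of the repeat libraries and of the random splits for the comparison of 6-120 with 96-120 hpf were chosen after the result was seen. In 10 of 110 pairs of a named gene and a treated group of 5, 1 embryo lay far from the other 4 by Dixon's ratio of its gap to the range (critical value 0.71), where independent normal values would give about 1 in 20, or 5.5. The ratio was taken on CPM, which need not be normal, and the genes share embryos and were chosen by their test. So 10 against 5.5 does not show an excess. With PFOA in 6-24 hpf, col4a3bpa had a ratio of 1, with 0.152 CPM in embryo 5 and 0 in the others. With PFOS in 6-48 hpf, atf3 had 0.779 (44.9 CPM in embryo 2, next 19.4). In 6-120 hpf the ratios were 0.866 for rtn4rl2a with PFOS (36.5 in embryo 3, next 12.4), 0.828 for sypa_1 (0.791 in embryo 3, next 0.136) and 0.715 for snu13a with PFOA (7.11 in embryo 2, next 2.37). With PFHxS in 6-120 hpf they were 0.926 for ugt5d1 (low at 4.38 in embryo 2, next 9.37), 0.819 for ca4b (12.6 in embryo 2, next 4.28) and 0.738 for tmem130 (low at 1.56 in embryo 4, next 3.47). In 96-120 hpf they were 0.822 for abcc12 with PFOA (46.6 in embryo 1, next 39.3) and 0.852 for cyp2k18 with PFHxS (56.4 in embryo 1, next 31). The response differed between 6-120 and 96-120 hpf, by the interaction test, in 134 genes for PFOS and 10 for PFOA.

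The first pattern weighed is that PFOS and PFOA called genes at every concentration in 6-24 hpf, with no gradient among treated embryos. The values go with VA embryos that stand apart from the VB embryos: against VB alone the PFOS calls at 20825 µg/L were 46, against VA alone 3875, and PFHxS and chlorpyrifos gained calls against VA alone too (444 and 2140). A shift common to all DMSO embryos of the window cannot be told apart, since the slope of the PFHxS profile on the PFOS and PFOA profile was 0.23 but ran from -0.01 to 0.48 with the control set used. A difference in developmental stage stays open as well: the median absolute correlation with the DMSO change from 24 to 48 hpf was 0.1, at the bound set for it, with 16 of 16 groups of the same sign. All groups share the same DMSO embryos, so their signs are not independent. The correlations ran from -0.16 to -0.06 with PFOS, -0.12 to -0.02 with PFOA and -0.12 to 0.02 with PFHxS. They thus did not separate PFOA from PFHxS. An effect of both compounds may remain for myh6, called at 20825 µg/L PFOS and 57325 µg/L PFOA against either set of DMSO embryos, and clutch or plate was not tested.

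The second pattern is that PFOS at 7 µg/L and PFOA at 16 µg/L in 6-120 hpf called as many genes as the highest concentrations. Profiles were correlated with the highest concentration of 24-120 and 48-120 hpf to test for labels in reverse order. For PFOS the lowest concentration had -0.174 and -0.265 and the highest 0.192 and 0.091, which argues against reversed labels, though the correlations are weak. For PFOA the lowest had -0.182 and -0.05 and the highest -0.024 and 0.009. The labelled highest PFOA group thus shows no likeness of its own, and the test cannot decide for PFOA. The highest of the 4 differences was -0.059. A shift of DMSO embryos common to the window would touch every group. Yet PFOS at 1639 and 506 µg/L and PFOA at 1687, 571 and 160 µg/L called no genes by edgeR. This argues against such a shift as the whole of the pattern. A part in it cannot be told apart, because the mean slope of these middle concentrations on the lowest was 0.45, between the bounds set. Developmental stage cannot be told apart either, at an absolute correlation of 0.1 with the DMSO change from 48 to 120 hpf. A response to low concentrations may remain, and neither plate nor clutch could be tested with the labels used here.

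The third pattern is that in 5 of 32 pairs of a first and a repeat library, the first was closer by chi-square to another embryo of its group than to the repeat. For PFOA 52 µg/L in 48-120 hpf and PFOS 33 µg/L in 96-120 hpf a library of another embryo is argued against. By the correlation of log2 CPM centred per gene, the own pair ranked 1 or 2 of 552 libraries sampled at 120 hpf for either library, and by chi-square per degree of freedom (6.422 and 8.529) each repeat lay closest to its own first library. For the other 3, DMSO 96-120 hpf (chi-square 16.472) and PFHxS 15 µg/L in 48-120 hpf (35.616) and 96-120 hpf (19.66), another embryo cannot be told apart: the own pair ranked as low as 11, and no library outside the pair came as close as like pairs do (correlation of at least 0.716). In the 27 like pairs the own pair ranked 1 for both libraries. A fault shared by these repeat libraries is a candidate explanation, and the values go with it: 4 of the 5 had another of the 5 as their closest library outside the pair, across treatments, against 0 of the other 27 repeats. What the fault would be was not tested. The median chi-square was 1.522 over all 32 pairs and 9.868 between embryos, and no biological explanation was tested.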

How the results depend on the processing

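The trend among treated embryos, the removal of embryo 5 of PFHxS 191 µg/L in 48-120 hpf and the removal of embryos with unlike repeats were added as alternatives after the data were seen. No called named gene turned its direction under any alternative run. Counts of genes called that moved by more than 1.5 times follow by setting. The cause was not tested, except that some settings leave fewer embryos or genes. Against the VA embryos alone, with fewer controls, counts were 3875 (PFOS), 1693 (PFOA), 444 (PFHxS), 2140 (chlorpyrifos) in 6-24 hpf and 1 (PFOS) in 6-48 hpf. VA alone gave 1 (PFOS), 8 (PFHxS) in 24-48 hpf and 3 (chlorpyrifos) in 6-120 hpf. Against VA they were also 75 (PFHxS) in 24-120 hpf and 172 (PFOS), 8 (PFOA), 137 (PFHxS) in 48-120 hpf. The last were 2 (PFOS), 9 (PFOA), 0 (chlorpyrifos) in 96-120 hpf. Against the VB embryos alone, with fewer controls, counts were 46 (PFOS), 75 (PFOA), 5 (chlorpyrifos) in 6-24 hpf and 2 (PFOA), 1 (chlorpyrifos) in 6-48 hpf. VB alone gave 17 (PFOS), 57 (PFOA), 1 (PFHxS) in 24-48 hpf and 842 (PFOS), 175 (PFOA), 56 (PFHxS), 3 (chlorpyrifos) in 6-120 hpf. It further gave 191 (PFOS), 320 (PFOA) in 24-120 hpf and 1205 (PFOS), 13 (PFOA), 23 (PFHxS), 120 (chlorpyrifos) in 48-120 hpf. The last were 4 (PFOS), 21 (PFOA), 6 (chlorpyrifos) in 96-120 hpf. By DESeq2 counts were 1 (PFHxS), 1138 (chlorpyrifos), 1 (PFOS against PFOA), 11 (PFOS against PFHxS), 2 (PFOA against PFHxS) in 6-24 hpf and 17 (PFOA) in 6-48 hpf. DESeq2 gave 5 (PFOS), 5 (PFOA) in 24-48 hpf and 30 (PFOA against PFHxS) in 6-120 hpf. It called 125 (chlorpyrifos) in 24-120 hpf and 13 (chlorpyrifos) in 48-120 hpf. DESeq2 further called 22 (PFOA), 36 (chlorpyrifos) in 96-120 hpf and 383 (PFOS), 89 (PFOA) between 6-120 and 96-120 hpf. With only the compound's own groups and DMSO in the model counts were 1 (PFHxS) in 6-24 hpf and 6 (PFOS), 2 (PFOA) in 6-48 hpf. This model gave 1 (PFOS) in 24-48 hpf and 343 (PFOA) in 24-120 hpf. It also gave 50 (PFHxS) in 48-120 hpf. With no filter on low counts they were 333 (PFOA), 1 (PFOA against PFHxS) in 6-24 hpf and 3 (chlorpyrifos), 7 (PFOA against PFHxS) in 6-120 hpf. Without the filter they were 1 (chlorpyrifos) in 96-120 hpf and 80 (PFOS), 1 (PFOA) between 6-120 and 96-120 hpf. With repeat libraries left out they were 2 (PFOS against PFHxS) in 6-24 hpf and 1 (chlorpyrifos) in 96-120 hpf, and with DESeq2 size factors 1 (PFOS against PFOA) in 6-24 hpf. The labels number embryos within each group but name no link between equal numbers. Over the windows, embryos of equal number had a median correlation of their deviations between -0.013 and 0.006, and embryos of other numbers between -0.016 and -0.005, so the numbers pair no samples. Treated embryos share numbers only with VA embryos. Against DMSO within a window, the block is thus close to VA alone with fewer controls, and is no separate check. With the replicate number as a block counts were 3537 (PFOS), 1656 (PFOA), 818 (PFHxS), 2059 (chlorpyrifos), 1 (PFOS against PFOA), 1 (PFOS against PFHxS) in 6-24 hpf and 3 (PFOS), 1 (PFHxS) in 6-48 hpf. The block gave 1 (PFOS), 8 (PFHxS) in 24-48 hpf and 4 (chlorpyrifos) in 6-120 hpf. It called 389 (PFOS), 174 (PFOA), 34 (PFHxS) in 24-120 hpf and 148 (PFOS), 8 (PFOA), 163 (PFHxS) in 48-120 hpf. Its other counts were 1 (PFOS), 13 (PFOA), 0 (chlorpyrifos) in 96-120 hpf and 2 (PFOS) between 6-48 and 24-48 hpf. The block also gave 53 (PFOS), 0 (PFOA) between 6-120 and 96-120 hpf. With 1 embryo number left out of each treated group in turn, and so fewer embryos, counts ranged over 570 to 2060 (PFOS), 133 to 574 (PFOA), 0 to 3 (PFHxS), 30 to 310 (chlorpyrifos), 0 to 1 (PFOS against PFOA), 0 to 26 (PFOS against PFHxS), 0 to 38 (PFOA against PFHxS) in 6-24 hpf and 3 to 31 (PFOS), 0 to 36 (PFOA), 1 to 4 (PFHxS) in 6-48 hpf. Leaving out each number likewise gave 0 to 4 (PFOS), 0 to 2 (PFHxS) in 24-48 hpf and 708 to 1323 (PFOS), 196 to 586 (PFOA), 61 to 107 (PFHxS), 2 to 10 (chlorpyrifos), 70 to 302 (PFOS against PFOA), 28 to 142 (PFOS against PFHxS), 1 to 64 (PFOA against PFHxS) in 6-120 hpf. In the next windows the ranges were 141 to 462 (PFOS), 156 to 756 (PFOA), 74 to 186 (PFHxS), 6 to 58 (chlorpyrifos) in 24-120 hpf and 342 to 688 (PFOS), 7 to 54 (PFOA), 43 to 100 (PFHxS), 0 to 2 (chlorpyrifos) in 48-120 hpf. Further ranges were 3 to 13 (PFOS), 9 to 30 (PFOA), 4 to 11 (PFHxS), 1 to 3 (chlorpyrifos) in 96-120 hpf and 43 to 82 (PFOS), 0 to 12 (PFOA) between 6-120 and 96-120 hpf. The last ranges were 0 to 1 (PFHxS) between 6-48 and 24-48 hpf. A tPOD is given where it moved by more than its bootstrap SD. For the tPOD in µg/L, the same removal gave 17.5 to 4220 (PFOS) in 6-48 hpf, 27.1 to 113 (PFOS), 2750 to 19500 (PFHxS) in 24-120 hpf, 116 to 13800 (PFHxS), 802 to 1870 (PFOS) in 48-120 hpf. In 6-120 hpf it gave 999 to 2920 (PFHxS), within the bootstrap SD. It left fewer than 25 genes, and so no tPOD, for PFOS in 6-48 hpf (without number 5), 24-48 hpf (1, 3, 4 or 5, with 355 without 2) and 96-120 hpf (1, 2, 3 or 5). It gave a tPOD where there was none for PFOA in 6-48 hpf (41100 without 4) and 48-120 hpf (30700 without 5), and for PFHxS in 6-24 hpf (111 without 5) and 24-48 hpf (63900 without 5). As the 10th percentile of benchmark doses the tPOD was 5.88 (PFOS), 15 (PFOA) in 6-24 hpf, 8.82 (PFOS) in 6-48 hpf and 12.5 (PFOS) in 24-48 hpf. The percentile gave 9.34 (PFOS) in 6-120 hpf, 3040 (PFOS) in 96-120 hpf and 2160 (PFHxS) in 24-120 hpf. As the lowest concentration with 25 called genes it was 7 (PFOS), 16 (PFOA) in 6-24 hpf, 7 (PFOS) in 6-48 hpf, 7 (PFOS) in 24-48 hpf and 7 (PFOS), 16 (PFOA), 7061 (PFHxS) in 6-120 hpf. This rule gave 506 (PFOS), 65395 (PFHxS) in 24-120 hpf, 6386 (PFOS), 191 (PFHxS) in 48-120 hpf and 74407 (PFOS) in 96-120 hpf. With no minimum fold it was 9.07 (PFOS) in 6-48 hpf, 13.4 (PFOS) in 24-48 hpf and 14.5 (PFOS) in 24-120 hpf. No minimum gave 363 (PFOS), 432 (PFHxS) in 48-120 hpf, 25200 (PFOS) in 96-120 hpf and 16.8 (PFOA) in 6-120 hpf. It gave a tPOD where there was none for PFHxS in 6-24 hpf (19.2), 6-48 hpf (17.4) and 24-48 hpf (12500). For PFOA it did so in 48-120 hpf (23600). With genes of a trend among treated embryos it was 2510 (PFOS), 5850 (PFOA) in 6-120 hpf, 347 (PFOS), 48600 (PFOA) in 24-120 hpf and 768 (PFOS) in 48-120 hpf. This trend gave 15100 (PFOS) in 96-120 hpf. Without embryo 5 of PFHxS 191 µg/L counts in 48-120 hpf were 1099 (PFOS) and 106 (PFHxS), and the tPOD was 357 (PFOS), 8030 (PFHxS) in 48-120 hpf. PFOA then had a tPOD there, 23400 from 34 genes. The 211 calls of gene lists fell to 17 with an estimated correlation. Of the 161 calls of named genes, some settings covered only a part. Lost and kept calls were 72 and 58 against VB and 31 and 99 against VA. They were 46 and 115 with the block, 17 and 144 with no filter and 10 and 151 without repeats. By DESeq2 they were 8 and 133, with DESeq2 size factors 3 and 158, and with the compound's own groups 18 and 92. Leaving out an embryo number ended 66 and kept 95 calls (number 1), 58 and 103 (2), 71 and 90 (3), 46 and 95 (4) and 45 and 96 (5). Chlorpyrifos has no embryos 4 and 5, so its calls are not among the last 2. Without embryos whose repeats were unlike, none of the 8 counts run moved by more than 1.5 times. Of the named calls run there, 15 were kept and 3 lost. In counts simulated for 5 embryos against 16 from DMSO means, 22% of simulated 1.5-fold changes were called, and 57.5% of simulated 2-fold differences between windows.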

Other observations

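The genes in this part were chosen after their values were seen, as were the groups, taken for having many calls below the highest concentration. At the lowest concentrations of 6-120 hpf, 3 genes of cartilage and notochord matrix were high: cmn stood at 117 CPM with PFOS at 7 µg/L against 33.2 in DMSO (log2 fold change 1.84 ± 0.31, adjusted p = 5e-05, n = 5 and 16) and matn3a at 162 against 47.5 (1.77 ± 0.28). With PFOA at 16 µg/L they stood at 1.42 ± 0.31 and 1.3 ± 0.28, and col9a1b at 1.67 with PFOS and 1.22 with PFOA. In the fixed list of cartilage, bone and notochord 6 of 16 genes rose with PFOS and 5 with PFOA, and its shift did not hold (adjusted p = 0.24 and 0.26 with an estimated correlation). More members of other lists were called: of 32 cytosolic ribosome genes 23 fell with PFOS and 12 with PFOA (adjusted p = 0.17 and 0.15), and of 19 genes of epidermis and keratins 8 and 6 fell (0.13 for each, with an estimated correlation). PFOS at 7 µg/L lowered cyt1l to 1960 from 4290 CPM (-1.13 ± 0.25, adjusted p = 0.0017) and msx1b (-1.07 ± 0.21, adjusted p = 0.00048). The 2 groups shared 466 raised and 215 lowered genes, where independent lists would share 27.8 and 12, and 76 or 220 raised and 20 or 83 lowered genes when each used other DMSO embryos. With its own highest concentration PFOS at 7 µg/L shared 240 raised and 191 lowered genes (32.6 and 18.1 for independent lists, 97 or 120 and 82 or 77 with split controls). PFOA at 16 µg/L shared 96 and 74 with its own (9.81 and 3.43 for independent lists, 13 or 17 and 16 or 10 with split controls). The numbers for independent lists are from the full lists. Lists with split controls differ in length, and no such number was computed for them. The PFOS group called 1593 genes in all, 600 against VB alone, 1736 against VA alone and 855 to 1232 with each embryo left out, and the PFOA group 1114, 153, 1221 and 441 to 1204. Cholinergic and neuronal genes rose in 15 of 23 cases with PFOS and 13 of 23 with PFOA at these concentrations, without the list's shift holding (adjusted p = 0.097 with an estimated correlation for each).

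PFHxS at 1790 µg/L in 24-48 hpf called 627 genes and raised the glucocorticoid-responsive genes fkbp5 to 53.6 from 11.1 CPM (2.44 ± 0.39, adjusted p = 0.00016, n = 5 and 16) and klf9 to 14.7 from 4.18 (1.94 ± 0.33, adjusted p = 0.00016). In the list of glucocorticoid and hypoxia genes 4 of 21 rose, and its shift did not hold (adjusted p = 0.23 with an estimated correlation). In the same group 11 of 22 cholinergic and neuronal genes and 5 of 12 heart muscle genes rose and 5 of 19 genes of epidermis and keratins fell, also without holding (adjusted p = 0.097, 0.13 and 0.1). The mitochondrial ribosomal RNA mt-rnr1 rose to 4190 from 1730 CPM (1.28 ± 0.29, adjusted p = 0.0053). The count was 186 to 498 with each embryo left out, 268 against VA alone and 938 against VB alone. PFHxS at 191 µg/L in 48-120 hpf called 1187 genes, and 0 by edgeR without embryo 5 (1716 at an unadjusted p under 0.05). In that group 12 of 18 innate immune and acute phase genes and 17 of 26 heat shock and unfolded protein genes rose, and neither list's shift held (adjusted p = 0.15 and 0.26 with an estimated correlation). In embryo 5 these 4 genes were high: il1b at 336 CPM against at most 1.72 in the other 4, mmp9 at 2320 against at most 7.56, mmp13a at 1140 against at most 3.87 and cxcl8a at 63.3 against at most 2. Of its raised genes 2 were shared with PFHxS at 65395 µg/L, where independent lists would share 2.85. PFOA at 571 µg/L in 24-120 hpf called 1119 genes, 160 without embryo 4, 523 against VB alone and 1037 against VA alone. PFHxS at 15 µg/L in 6-48 hpf called 570, with 48 without embryo 1, 22 against VB alone and 961 against VA alone.

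Each count was set against 100 splits of the same embryos, drawn at random with the real one included and fitted on the groups compared alone, so most real counts differ from those above. Below, each bracket gives the splits with as many genes, the real count and the highest other. A count is called rare here where 1 or 2 of 100 splits reached it. With the real split included, 1 of 100 is the lowest share possible. Where 2 of 100 did, 1 other split called as many genes or more. Shares were not adjusted for the number of comparisons, so a rare count argues against chance but does not exclude it. Rare in 6-24 hpf were counts for PFOS (2 of 100, 1245, 1966), PFOA (1 of 100, 366, 9), chlorpyrifos (2 of 100, 33, 1136). So was that in 6-48 hpf for PFOS (1 of 100, 4, 2). Counts in 6-120 hpf were rare for PFOS (1 of 100, 980, 41), PFOA (1 of 100, 354, 22), PFHxS (1 of 100, 37, 14). Rare there too were PFOS against PFOA (1 of 100, 131, 11), PFOS against PFHxS (1 of 100, 51, 32). Counts were rare likewise in 24-120 hpf for PFOS (2 of 100, 266, 307), PFOA (1 of 100, 69, 11). In that window they were also rare for PFHxS (1 of 100, 136, 81), chlorpyrifos (1 of 100, 20, 13). The same holds in 48-120 hpf for PFOS (1 of 100, 710, 55), PFOA (1 of 100, 25, 12), PFHxS (1 of 100, 83, 13). Further, counts were rare in 96-120 hpf for PFOA (2 of 100, 19, 37), PFHxS (1 of 100, 5, 3). Lastly, they were rare between 6-120 and 96-120 hpf for PFOS (1 of 100, 134, 7), PFOA (2 of 100, 10, 10). Splits between windows shuffled treated and DMSO embryos within each window, which takes the exposure effect out of both. They thus do not test whether the response was the same in both windows. Where at least 5 of 100 splits reached the count, it was not rare. Chance cannot be excluded either in 96-120 hpf for PFOS (5 of 100, 5, 20). Nor can it be in 6-48 hpf for PFOA (13 of 100, 1, 5), PFHxS (11 of 100, 1, 38). Nor is it excluded in 6-24 hpf for PFHxS (17 of 100, 1, 1656). Chance is not excluded in 6-120 hpf for chlorpyrifos (11 of 100, 3, 32), PFOA against PFHxS (7 of 100, 4, 13). Where edgeR called 0 genes in the real split, all 100 of 100 splits have as many by necessity, so the splits decide nothing. These comparisons, with the highest other count, are in 24-48 hpf PFOS (6), PFOA (13), PFHxS (19) and chlorpyrifos (572), and chlorpyrifos in 6-48 hpf (8), 48-120 hpf (8) and 96-120 hpf (11). They are also, in 6-24 hpf, PFOS against PFOA (10), PFOS against PFHxS (87) and PFOA against PFHxS (51). Between 6-48 and 24-48 hpf they are PFOS (34), PFOA (3) and PFHxS (40), and between 6-120 and 96-120 hpf PFHxS (2). Splits of PFOS, PFHxS and chlorpyrifos embryos with DMSO that called 1966, 1656 and 1136 genes in 6-24 hpf, and 572 for chlorpyrifos in 24-48 hpf, point to a structure among the embryos other than the exposure.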
